A study of Mus musculus with 9 samples.

How the data were processed

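Testis RNA from ICR mice, an outbred stock, aged 8 weeks was sequenced after an injection of PBS (Control), AZ82 at 1 µM or CW069 at 50 µM. Each group held 3 libraries, 9 in all. The labels give 3 samples per group and do not say whether the samples came from separate animals, so every p-value measures the spread between these samples, which may be technical in part. No sequencing batch, date or time after injection is given.

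The deposited table holds a count of reads per gene for each library, with no normalization by the authors. The values were checked to be whole numbers at or above 0, and each library's own deposited counts matched its column of the joint table in all 19991 genes. The submitters' processing notes name Trimmomatic for trimming, HISAT2 for alignment to GRCm39 and HTSeq for counting, without settings. The labels name a stranded mRNA library kit; the strand setting of the counting is not given. Reads shared by near-identical genes can be lost or misplaced in such counts, so values of Kifc1 and Kifc5b, Hba-a1 and its copy, Hsd3b6 and Hsd3b1, the tubulins and predicted gene families carry that uncertainty. Symbols were looked up in a RefSeq table (19819 found) and a GENCODE transcript table (19143 found) of an earlier build, used for names, gene order, transcript length and GC content alone. The table holds 0 mitochondrially encoded genes.

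Totals ran from 13856070 to 18102593 counts per library. Genes with low counts were removed with filterByExpr by group, which left 15834 genes. Counts were scaled with TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group over all 9 libraries, which leaves 6 residual degrees of freedom. The quasi-likelihood F test, which is two-sided, was used for 4 comparisons: AZ82 against Control, CW069 against Control, CW069 against AZ82, and the mean of both inhibitors against Control. P-values were adjusted over all genes tested by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. Fold changes are log2 values with their SE; group levels are counts scaled to library size (CPM) with SD over 3 libraries. The median 95% interval of a log2 fold change between groups of 3 reached 0.28 to either side, a factor of 1.21.

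A set of 38 gene lists, covering germ cell stages, somatic and blood cell types, motors and the spindle, and stress and signalling responses, was fixed before the data were examined, as were the tests, the rule for named genes and the other settings to be tried, except where said. Of these, 36 lists had at least 5 tested members. Each was tested with camera (limma 3.58.1), which compares a list with all other genes at a preset inter-gene correlation of 0.01, with adjustment over the 36 lists of a comparison. Camera with an estimated correlation and fry, a test of whether a list's genes move on balance in 1 direction, were run beside it, with fry's mixed test for change in either direction. P-values of genes were also adjusted over each list alone, with no further correction for the number of lists or comparisons. Some calls made in this way can therefore arise by chance.

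The genes named were Kifc1 and Kifc5b in every comparison; all called genes where there were few; the 5 genes per direction with the smallest p among those with a mean of at least 1 CPM, no overlap between the groups and a symbol other than that of a predicted gene; and up to 4 members of a list past its test, by smallest p. Members of a list that passed when adjusted over the list alone are named as well. Other genes named were chosen after their values were seen: Prm1, Prm2, Tnp1, Hsd3b1, Cyp17a1, Klk1b21, Inha, the genes called only by another tool or without 1 library, and members named by their level in 1 library.

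The agreement between inhibitors was measured as Pearson and Spearman correlations of log2 fold changes across genes, set beside 20 simulations of unchanged groups against the same Control libraries. The pipeline was tested on simulated counts modelled on all 9 libraries, with changes placed in the AZ82 group and tested against Control. It recovered 53.7% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 15 false calls among 172; limma-voom made 13 false calls among 167 and DESeq2 30 among 195. With no simulated change, 4.61% of genes had an unadjusted p under 0.05 and 0 genes and 0 lists were called. Genes were simulated independently of each other. The list results of these simulations thus do not show how often correlated genes would bring a list past the test. A simulated shift of -0.25 in the Leydig list was recovered by camera with the preset correlation (adjusted p = 3.37e-10), with an estimated correlation (adjusted p = 0.0223) and by fry (adjusted p = 0.0383).

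The other settings fixed in this way were RLE factors or library size in place of TMM, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, fits of the compared groups alone, other thresholds, replicate number as a block, and each library left out in turn. Removal of each library's trend with transcript length and GC content, CW069 1 and 2 summed as 1 library, and an estimated correlation with each library left out in turn were chosen after seeing the data. Splits of the libraries into other groups were run for the counts of called genes, of genes at an unadjusted p under 0.05 and of lists past the test, and for the correlation of the inhibitors' fold changes. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. No library was left out of the comparisons.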

Results

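The series profiled testis gene expression after inhibition of KIFC1, a minus-end-directed kinesin that cross-links spindle microtubules and clusters centrosomes, and that takes part in shaping the spermatid head. AZ82 and CW069 are inhibitors known here by their code names. There were 3 libraries from PBS-injected mice (Control), 3 after AZ82 at 1 µM and 3 after CW069 at 50 µM, from 8-week-old ICR animals. Total counts were 14510001, 15507318 and 13856070 in Control 1 to 3, 14080156, 14386351 and 14241754 in AZ82 1 to 3, and 14669424, 14318774 and 18102593 in CW069 1 to 3. Between 18314 and 18553 of the 19991 genes had counts, and 15834 were tested.

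The libraries differed in ways that the groups do not account for. Control 3 held fewer transcripts of late spermatids: Prm2, a protamine that packs sperm DNA, stood at 1174 CPM there against 4417 and 3984 CPM in Control 1 and 2. Over the elongating spermatid list, Control 3 had a median log2 ratio of -0.75 to the mean of the other Control libraries, and 36 of 40 members were lower than in both. Its red blood cell list lay at -0.95, with 5 of 5 members lower than in both. Control 1 had the highest macrophage list level, 0.47 on the log2 scale against the mean of all libraries, and AZ82 2 the highest adipocyte list level, 0.72. CW069 1 and 2 were closer to each other than any other pair of libraries, with 2 genes that differed 10-fold or more against 11 to 29 in the 35 other pairs.

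**Figure D1:**
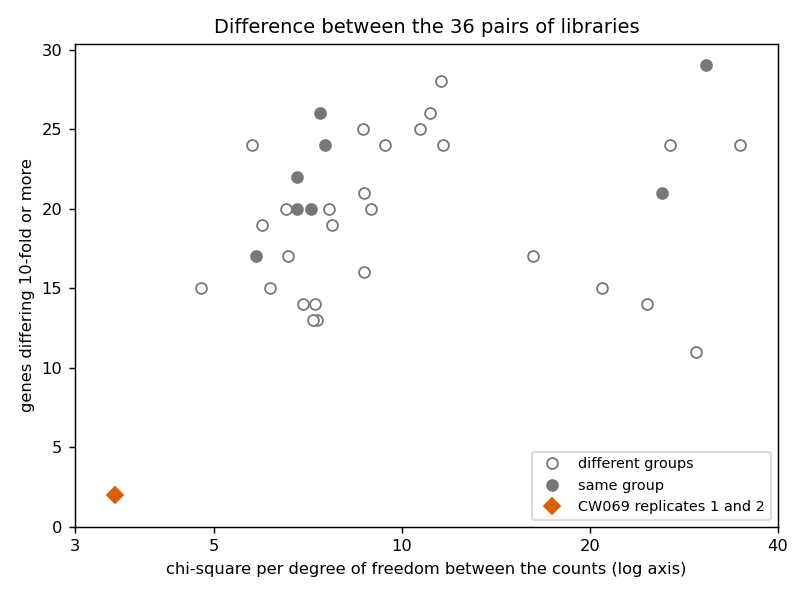
Each point is 1 of the 36 pairs of libraries; the x axis shows chi-square per degree of freedom between their counts (log axis) and the y axis the number of genes that differ 10-fold or more. CW069 1 and 2 sit apart at 3.48 and 2 genes, while the other pairs lie between 4.76 and 34.8 and between 11 and 29 genes.

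The target transcript came first. Kifc1 was at 8.66 ± 0.816 CPM in Control, 9.33 ± 0.280 CPM after AZ82 and 9.57 ± 0.820 CPM after CW069 (SD, n = 3 each). Its log2 fold change was 0.11 for AZ82 (95% interval -0.15 to 0.36; edgeR adjusted p = 0.784) and 0.15 for CW069 (-0.11 to 0.40; adjusted p = 0.777), so no difference larger than the spread between libraries was detected. Both intervals exclude a change of 1.5-fold. With a library left out the values stayed above 0: for AZ82 0.18 without Control 2 and 0.05 without Control 3, and for CW069 0.23 without Control 2, 0.09 without Control 3 and 0.07 without CW069 3. Kifc5b, a near-identical copy with which Kifc1 can share reads, was at 10.03 ± 0.967, 10.03 ± 0.541 and 9.73 ± 0.672 CPM. The inhibitors act on the protein, and its transcript need not move.

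AZ82 against Control asks how testis expression differed after the first inhibitor. Genes of spermatid differentiation rose as lists. The elongating spermatid and sperm list, which holds protamines and sperm structural proteins, rose by a median log2 of 0.27, with 38 of 40 tested members above 0 (camera adjusted p = 5.79e-10; adjusted p = 0.465 with an estimated correlation). Its examples are the transition protein gene Tnp2 (0.58 ± 0.23, SE, but 0.31 without Control 3) and the sperm glycolytic enzyme gene Pgam2 (0.32 ± 0.08, SE). The acrosome and round spermatid list rose by 0.12, with 38 of 46 above 0 (adjusted p = 1.38e-06; adjusted p = 0.457 with an estimated correlation), among them the acrosomal protease gene Pcsk4 (0.25 ± 0.08) and Sun5, which anchors the sperm head to the tail (0.25 ± 0.09). The axoneme and flagellum list rose by 0.10 over 54 members (adjusted p = 0.000172), the manchette list, whose microtubules shape the spermatid head, by 0.08 over 42 (adjusted p = 0.00117), and the tubulins by 0.14 over 18 (adjusted p = 0.00321). These last 3 lists each had an adjusted p = 0.457 with an estimated correlation. Cfap45 (0.28 ± 0.08) and Tekt1 (0.25 ± 0.09, but 0.13 without AZ82 3), which encode proteins inside flagellar microtubules, were among the axoneme members with the smallest p, and Tuba8 (0.32 ± 0.13, but 0.15 without Control 3) among the tubulins. Control 3, low in late spermatid transcripts, belongs to the Control group here: without it the elongating spermatid median was 0.04 (camera adjusted p = 0.0220) and the acrosome median 0.07 (0.000107). All 5 lists stayed past the test with each library left out in turn.

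The Leydig, spermatogonia and Sertoli cell lists fell after AZ82 as groups, but only spermatogonia lay below every Control library in each AZ82 library. On the log2 scale against the mean of all libraries, the Leydig level of AZ82 2 was 0.12, above every Control library (0.09 to 0.11). AZ82 1 and 3 lay below them (-0.18 and -0.08). Sertoli levels overlapped, at -0.14, -0.02 and 0.00068 in AZ82 1 to 3 against 0.16, -0.0053 and -0.03 in Control 1 to 3. All list levels here are relative to the total counts of a testis library. A changed share of a cell type and changed expression per cell were not told apart, for lists that fell or rose, in any comparison. The Leydig and steroidogenesis list fell by a median of 0.17 on the log2 scale, with 23 of 30 members below 0 and 7 of these at an unadjusted p under 0.05 (camera adjusted p = 0.000172; adjusted p = 0.457 with an estimated correlation). Star, which carries cholesterol into mitochondria, had a log2 fold change of -0.36 ± 0.10 (155 ± 16.6 against 199 ± 19.0 CPM), Nr5a1, a master regulator of steroidogenic genes, -0.30 ± 0.08, and Cyp11a1, the side-chain cleavage enzyme, -0.25 ± 0.08. The spermatogonia list had a median of -0.13, with 21 of 25 below 0 (adjusted p = 0.00185; adjusted p = 0.402 with an estimated correlation), including Stra8, needed for entry into meiosis (-0.32 ± 0.11), and Ret, a receptor for self-renewal signals (-0.37 ± 0.16). The Sertoli cell list had a median of -0.12, with 25 of 29 below 0 (camera adjusted p = 0.00185, and 0.457 with an estimated correlation). Its members include Cst12 (-0.47 ± 0.12) and Kitl, the stem cell factor that germ cells need. Kitl had -0.60 ± 0.27, but -0.94 without AZ82 2 and -0.39 without AZ82 3. Smaller falls were seen in the oxidative stress list (median -0.07; adjusted p = 0.0283), the extracellular matrix list (-0.06; 0.0283) and the blood-testis barrier list (-0.06; 0.0491), with an adjusted p = 0.457, 0.779 and 0.457 with an estimated correlation. The Leydig median was -0.07 without AZ82 1 and -0.27 without AZ82 2, past the test in both fits; the spermatogonia median was -0.20 without AZ82 3. Without Control 1 the Sertoli list had an adjusted p = 0.0586, and the matrix median was 0.01 (0.726). That median was -0.14 without Control 2, -0.09 without Control 3, -0.02 without AZ82 2 and -0.20 without AZ82 3. The matrix list was also lost without AZ82 1 or AZ82 2 (0.230 and 0.307), the oxidative stress list without Control 1, Control 2 or AZ82 1 (0.0544 to 0.123), and the barrier list without Control 1, Control 2, AZ82 1, AZ82 2, CW069 1 or CW069 3 (0.0546 to 0.215).

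Gene by gene, edgeR called 0 genes higher and 0 lower after AZ82, with a smallest adjusted p of 0.0766, that of Slc1a7, a lower gene with a mean under 1 CPM. At an unadjusted p under 0.05 there were 640 higher and 759 lower genes, against 792 expected by chance in all; DESeq2 called 2 higher and 3 lower, and limma-voom 0 and 1. In 15.3% of genes the groups did not overlap, against 10% by chance. Among genes with a mean of at least 1 CPM, no overlap between the groups and a symbol other than that of a predicted gene, the smallest p of the higher ones belonged to Ttc22 (1.08 ± 0.16; 8.39 ± 0.964 against 3.98 ± 0.686 CPM; adjusted p = 0.317), followed by Zmiz2, a transcriptional coactivator (0.42 ± 0.08; 330 ± 18.1 against 246 ± 13.1 CPM), the histone deacetylase gene Hdac4 (0.44 ± 0.09), Fam166c (0.54 ± 0.11) and the cytokine gene Il11 (0.63 ± 0.14). Of the lower ones it belonged to Mtarc2, a mitochondrial reductase (-0.50 ± 0.08; adjusted p = 0.392), followed by Ptgr1, a prostaglandin reductase (-0.47 ± 0.09), the osteopontin gene Spp1 (-1.54 ± 0.28), Orc1 of the replication origin complex (-0.81 ± 0.15) and the copper transporter gene Slc31a1 (-0.34 ± 0.07). Adjusted over the list alone, 1 gene passed: Hba-a1, an alpha globin (-0.94 ± 0.26; adjusted p = 0.0207), in the red blood cell list of 5; this call was lost without Control 1, Control 2, AZ82 1 or AZ82 3 (0.0532 to 0.101).

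CW069 against Control asks the same of the second inhibitor. The Leydig list stood out again, with a median log2 fold change of -0.11 and 22 of 30 members below 0 (camera adjusted p = 7.55e-05; adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone, 6 of its 30 members passed, all lower, against 0 over all genes. Hsd3b6, an enzyme of androgen synthesis in adult Leydig cells, was at 24.9 ± 1.04 CPM against 54.3 ± 13.3 CPM in Control (log2 fold change -1.13 ± 0.16; adjusted p = 0.000819 over the list alone and 0.151 over all genes). The others were Cyp11a1 (-0.38 ± 0.08; 280 ± 13.5 against 365 ± 25.9 CPM), Nr5a1 (-0.28 ± 0.08), Star (-0.31 ± 0.10), the ferredoxin reductase gene Fdxr (-0.41 ± 0.13), which feeds electrons to steroidogenic cytochromes, and the estrogen sulfotransferase gene Sult1e1 (-0.85 ± 0.26). Hsd3b1, a paralog with which Hsd3b6 can share reads, was at 182 ± 9.35 against 218 ± 17.0 CPM. With a library left out the Leydig list stayed past the test, with a median of -0.07 without Control 1, -0.18 without Control 2 and -0.21 without CW069 1. Of its members past the test when adjusted over the list alone, Hsd3b6 and Cyp11a1 stayed so in 9 of 9 such fits, and the other 4 in 2 to 4 of them (highest adjusted p = 0.141).

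Immediate early genes rose after CW069, with a median of 0.17 and 25 of 33 members above 0 (camera adjusted p = 0.000773; adjusted p = 0.450 with an estimated correlation). Jund, an AP-1 subunit, passed when adjusted over the list alone (0.53 ± 0.10; 63.5 ± 2.89 against 44.0 ± 7.00 CPM; adjusted p = 0.0104, lost without CW069 2 at 0.0668); Nr4a1, an orphan nuclear receptor, had 0.32 ± 0.11, but 0.21 without CW069 3, and the phosphatase gene Dusp5 0.56 ± 0.17. The spermatid lists rose here too: acrosome and round spermatids by a median of 0.09 (37 of 46 above 0; adjusted p = 7.55e-05), axoneme by 0.07 (0.00119), tubulins by 0.08 (0.00711), manchette by 0.05 (0.0338) and elongating spermatids by 0.15 (8.21e-06). With an estimated correlation they had an adjusted p = 0.694, 0.694, 0.487, 0.694 and 0.705. Among their members were the flagellar spoke gene Rsph3a (0.35 ± 0.09) and the sperm ion channel gene Catsper4 (0.23 ± 0.07). The macrophage and antigen presentation list had a median of -0.21, with 24 of 29 below 0 (adjusted p = 0.00193; adjusted p = 0.705 with an estimated correlation), among them the Fc receptor chain gene Fcer1g (-0.81 ± 0.23). Control 1 was highest in this list, and without it the median was -0.07 (adjusted p = 0.460); without CW069 3 it was -0.11, past the test. The apoptosis list had a median of -0.09, with 31 of 40 below 0 (adjusted p = 0.00371; adjusted p = 0.450 with an estimated correlation); Bcl2l11, which promotes cell death, had -0.77 ± 0.23, but -0.44 without Control 1. The list holds genes that promote cell death and genes that oppose it, so its fall gives no direction for cell death. Bcl2l2, which opposes it, was at 30.9, 31.5 and 28.6 CPM in CW069 1 to 3, against 34.6, 33.6 and 35.2 CPM in Control 1 to 3. The apoptosis median was -0.14 without Control 2. Nuclear genes of oxidative phosphorylation had a median of -0.06, with 55 of 81 below 0 (adjusted p = 0.0206; adjusted p = 0.826 with an estimated correlation). Without Control 3, 5 of the 10 lists stayed past the test (acrosome, axoneme, Leydig, macrophages and immediate early genes), the acrosome median was 0.04 and the elongating spermatid median -0.00027 (adjusted p = 0.138). The latter was 0.28 without Control 1, 0.26 without Control 2 and 0.10 without CW069 3, past the test each time. Other losses were the axoneme list without CW069 3 (median 0.03; 0.218), tubulins without CW069 1 (0.0628), oxidative phosphorylation without Control 2, CW069 2 or CW069 3 (0.0726 to 0.309), and the manchette list without Control 1, Control 2, AZ82 2, CW069 1 or CW069 3 (0.0515 to 0.335). The oxidative phosphorylation median was -0.04 without CW069 2 or CW069 3, and the manchette median 0.03 without CW069 3.

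edgeR called 0 genes higher and 0 lower after CW069, with a smallest adjusted p of 0.114, again that of Slc1a7. At an unadjusted p under 0.05 there were 574 higher and 588 lower genes; DESeq2 called 13 higher and 14 lower, and limma-voom 0 in each direction. Groups did not overlap in 13.4% of genes, against 10% by chance. By the same rule the higher genes with the smallest p were Ankrd44 (0.69 ± 0.11; adjusted p = 0.296), Zmiz2 (0.46 ± 0.08), Ttc22 (0.88 ± 0.16), the protocadherin gene Dchs1 (1.37 ± 0.26) and the glycosyltransferase gene Galnt17 (0.82 ± 0.15). Dchs1 was at 21.4 and 24.6 CPM in CW069 1 and 2, the closest pair of libraries. It was at 10.5 CPM in CW069 3, against 6.61 to 7.80 CPM in Control. Besides Hsd3b6, the lower genes were the interferon-inducible DNA sensor Ifi204 (-1.79 ± 0.26; adjusted p = 0.151), Acadsb of branched-chain amino acid breakdown (-0.41 ± 0.07), the sorting nexin gene Snx15 (-1.11 ± 0.22) and Esd, an esterase (-0.55 ± 0.11). Adjusted over the list alone, 9 genes passed in all: the Leydig members and Jund above, Ebp of cholesterol synthesis (-0.38 ± 0.09) and the autophagy gene Atg2a (-0.58 ± 0.13). Ebp and Atg2a each passed in 3 of 9 fits with a library left out (highest adjusted p = 0.183 and 0.177). Each was the only call of its list, and no correction was made over the lists. Without Control 1, edgeR called Hsd3b6 (adjusted p = 0.00162; range 1.04e-06 to 0.833 over its 20 alternatives).

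**Figure D2:**
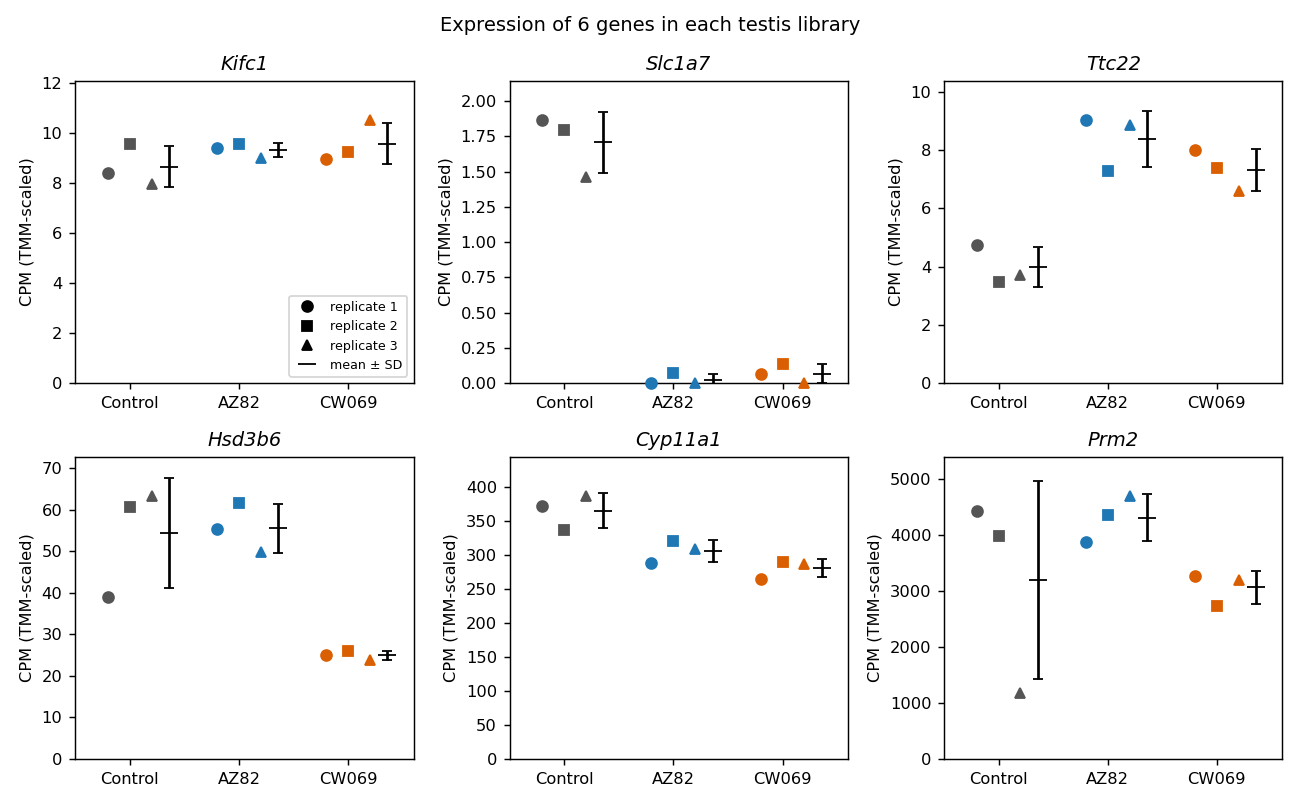
Level in CPM (y axis, counts scaled to library size) of 6 genes in each of the 9 libraries, by group on the x axis; points are libraries and bars the group mean ± SD (n = 3). Slc1a7 has a mean of 1.71 CPM in Control, 0.0238 CPM after AZ82 and 0.0685 CPM after CW069, and Prm2 is low in Control 3 (1174 CPM).

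The mean of both inhibitors against Control asks how the treated groups together differed from Control, and here 1 gene passed over all genes. Slc1a7, a glutamate transporter known from the retina, fell from 1.71 ± 0.215 CPM in Control to 0.0238 ± 0.0412 CPM after AZ82 and 0.0685 ± 0.0684 CPM after CW069 (SD, n = 3 each; log2 fold change -5.14 ± 0.49; edgeR adjusted p = 0.00924). The Control libraries held 27, 28 and 22 counts, and the 6 inhibitor libraries 0 to 2 each, 4 in all; the ratio was 37.7-fold with a 95% counting interval of 14.2 to 142. The call did not survive leaving out AZ82 1, AZ82 2, AZ82 3 or CW069 1 (adjusted p = 0.0557, 0.0626, 0.0518 and 0.0761), with a log2 fold change of -4.92 or further from 0, and 4 of the 50 nearest tested genes, Ttc22 and Orc1 among them, had an unadjusted p under 0.01. DESeq2 called 5 higher and 10 lower genes and limma-voom 0 and 1, and 1516 genes had an unadjusted p under 0.05.

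A list past the test on this mean need not be past it with each inhibitor. Of the 11 lists here, the Leydig, acrosome, axoneme, tubulin, manchette and elongating spermatid lists passed with each inhibitor too. The Leydig list had a median of -0.16, with 22 of 30 below 0 and 6 members, Cyp11a1, Nr5a1, Hsd3b6, Star, Fdxr and Sult1e1, past the test when adjusted over the list alone (camera adjusted p = 8.83e-06; adjusted p = 0.287 with an estimated correlation). Hsd3b6 was at 55.5 CPM after AZ82 against 54.3 CPM in Control, so its value here came from CW069. The list lay below every Control library in 5 of 6 inhibitor libraries and above every Control library in 1, AZ82 2. The acrosome list rose by 0.11 (adjusted p = 7.08e-07), axoneme by 0.09 (6.30e-05), tubulins by 0.12 (0.00216) and manchette by 0.07 (0.00216). Without Control 3 the acrosome median was 0.04, past the test (0.000555). With an estimated correlation they had an adjusted p = 0.401, 0.414, 0.287 and 0.401. The tubulin level lay above every Control library in 6 of 6 inhibitor libraries, the acrosome and manchette levels in 5 of 6 each. The elongating spermatid level did so in 4 of 6 and the axoneme level in 3 of 6. Elongating spermatids rose by 0.19 (adjusted p = 1.46e-09; adjusted p = 0.534 with an estimated correlation), but without Control 3 the median was -0.00080 (adjusted p = 0.865), against 0.33 without Control 1 and 0.31 without Control 2. Immediate early genes rose by 0.13 (adjusted p = 0.00786; adjusted p = 0.287 with an estimated correlation), among them Nr4a1 (0.36 ± 0.09), at 37.5 ± 4.15 CPM in Control, 49.1 ± 1.56 CPM after AZ82 and 46.9 ± 6.22 CPM after CW069. Without CW069 2 the median of this list was 0.08, past the test, and after AZ82 alone it was not past the test (adjusted p = 0.170). Medians were -0.12 for spermatogonia (adjusted p = 0.0234), -0.07 for apoptosis (0.00786), -0.21 for macrophages (0.00429) and -0.06 for oxidative stress (0.0256), whose adjusted p = 0.287, 0.287, 0.668 and 0.411 with an estimated correlation. With 1 inhibitor, spermatogonia were not past the test after CW069 (0.358), apoptosis after AZ82 (0.0619), macrophages after AZ82 (0.0517) or oxidative stress after CW069 (0.0959). Single libraries decided some of these: after AZ82 macrophages passed without Control 3 (median -0.35; adjusted p = 0.000381; adjusted p = 0.528 with an estimated correlation) and without Control 2, AZ82 2, AZ82 3, CW069 2 or CW069 3 (0.0126 to 0.0482), and apoptosis without Control 2 or AZ82 3 (0.0337 and 0.0320). Oxidative stress passed after CW069 without CW069 1 (0.0249). For both inhibitors together, without Control 1 the macrophage median was -0.06 (adjusted p = 0.602), without Control 3 it was -0.34, without Control 2 or AZ82 2 the spermatogonia list had an adjusted p = 0.145 and 0.0714, and without Control 3 the apoptosis list 0.0609; the apoptosis median was -0.14 without Control 2. The oxidative stress list was lost without Control 1, Control 2, AZ82 1 or CW069 3 (0.0576 to 0.0953), its median was -0.10 without Control 3, and the Leydig median was -0.10 without Control 1, past the test. Adjusted over the list alone, Cst12 of Sertoli cells (-0.44 ± 0.10) and the mitochondrial chaperone gene Hspd1 (-0.31 ± 0.07) passed as well, 8 genes in all. With a library left out, Cyp11a1 kept this call in 9 of 9 fits. Star, Nr5a1 and Hsd3b6 lost it without Control 2 (0.0567 each) and Hsd3b6 without Control 3 (0.0581), while Fdxr, Sult1e1, Cst12 and Hspd1 kept it in 2 to 4 fits (highest adjusted p = 0.199).

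Several lists passed for both inhibitors only with a library left out. Sertoli cells, with a median of -0.06 and an adjusted p = 0.0793 with all libraries, passed without Control 3, AZ82 2, CW069 1 or CW069 2 (0.0115 to 0.0477). Oxidative phosphorylation, with -0.03 (0.0582), passed without Control 1, AZ82 1, AZ82 2 or CW069 1 (0.00286 to 0.0327), and after AZ82 alone without AZ82 2 (0.0334). Extracellular matrix passed without Control 2 or AZ82 3 (0.00988 and 0.0216), cell cycle without Control 1 or CW069 1 (0.0135 and 0.0271), spindle checkpoint without Control 1 (0.0173) and ribosomal proteins without CW069 1 (0.0456), all with medians below 0.

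By the same rule, the genes higher with both inhibitors were Ttc22 (0.98 ± 0.14; adjusted p = 0.270), Zmiz2 (0.44 ± 0.07), the kinase gene Sik1 (0.68 ± 0.13), the RNA-binding protein gene Rbm47 (0.42 ± 0.08) and Amer2 (0.27 ± 0.05). The lower ones were Ifi204 (-1.27 ± 0.20; adjusted p = 0.350), Ptgr1 (-0.44 ± 0.07), Acadsb (-0.33 ± 0.06), Orc1 (-0.68 ± 0.13) and Vwa5a (-0.74 ± 0.15). None of these 10 passed over all genes with edgeR. Groups did not overlap in 5.11% of genes, against 2.38% by chance.

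**Figure D3:**
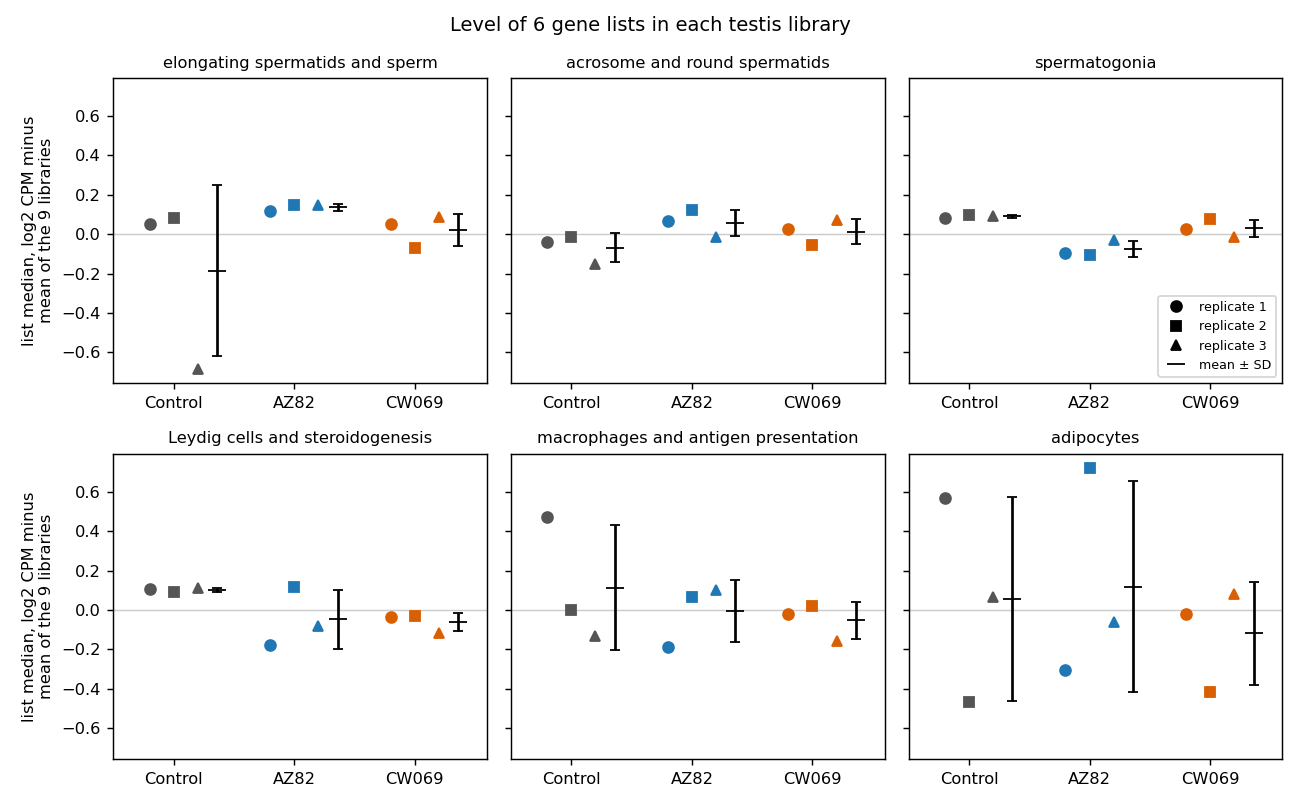
Median log2 level of 6 gene lists (y axis, relative to the mean of all 9 libraries) in each library, by group on the x axis; points are libraries and bars the group mean ± SD (n = 3). Control 3 lies far below the other libraries in elongating spermatids, Control 1 is highest in macrophages (0.47) and AZ82 2 in adipocytes (0.72).

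CW069 was set against AZ82 as given, at 50 µM and 1 µM, so compound and dose differ together. Hsd3b6 was lower after CW069 (24.9 ± 1.04 against 55.5 ± 5.89 CPM; log2 fold change -1.16 ± 0.16, 95% interval -1.51 to -0.80). It passed when adjusted over the list alone (adjusted p = 0.000663) and not over all genes (0.255), although a fit of these 6 libraries alone called it (0.00163; range 2.24e-07 to 1.00 over its 20 alternatives). Of the 30 Leydig members, 3 others had an unadjusted p under 0.05: Cyp17a1, an enzyme of androgen synthesis (-0.25 ± 0.10; 704 ± 37.5 against 835 ± 106 CPM; -0.14 without AZ82 2), Klk1b21 (0.79 ± 0.31, but 1.27 without AZ82 2) and the inhibin gene Inha (0.38 ± 0.16). Star differed by 0.05 (-0.16 to 0.27), Nr5a1 by 0.02 (-0.16 to 0.20) and Cyp11a1 by -0.13 (-0.29 to 0.04). Jund was higher after CW069 (0.50 ± 0.10; 63.5 ± 2.89 against 44.8 ± 1.04 CPM; adjusted p = 0.0154 over the list alone), as was Hba-a1 (0.86, 0.29 to 1.44; 0.0349 over the list alone); 3 genes passed that way in all. With a library left out, Hsd3b6 kept this call in 9 of 9 fits. Jund lost it without any AZ82 library, CW069 2 or CW069 3 (0.0543 to 0.0881). Hba-a1 lost it without AZ82 1, AZ82 3 or CW069 1 (0.114 to 0.157), and its log2 fold change was 0.52 without CW069 1.

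Of the lists, Sertoli cells rose with CW069 relative to AZ82 by a median of 0.10, with 23 of 29 above 0 (camera adjusted p = 0.00151; adjusted p = 0.855 with an estimated correlation), including Fshr, the receptor for follicle-stimulating hormone (0.41 ± 0.16). Spermatogonia rose by 0.13 (adjusted p = 0.0492; 0.855 with an estimated correlation), with Gfra1, a stem cell receptor, at 0.41 ± 0.18 (0.26 without CW069 3), and extracellular matrix by 0.06 (adjusted p = 0.0319; 0.855 with an estimated correlation). The interferon list had a median of -0.20, with 29 of 34 below 0 (adjusted p = 0.00151), including Ifit1 (-0.81 ± 0.33), and adipocytes -0.36, with 11 of 12 below 0 (adjusted p = 0.0492). Both of these also had an adjusted p = 0.855 with an estimated correlation. With a library left out, the Sertoli list alone of these 5 stayed past the test in each fit, with a median of 0.19 without CW069 3, while the adipocyte median was 0.05 without AZ82 2 (adjusted p = 0.983), -0.25 without CW069 2 (0.362) and -0.59 without CW069 3 (0.0637). The Sertoli level, against the mean of all libraries, was 0.14 and 0.08 in CW069 1 and 2, the closest pair. In CW069 3 the level was -0.06, against -0.14, -0.02 and 0.00068 in AZ82 1 to 3. Each such fit keeps a library of that pair, so it cannot show whether the Sertoli rise rests on the pair. The interferon list was lost without AZ82 2 or CW069 3 (median -0.10 in both; 0.264 and 0.175), and its median was -0.31 without AZ82 1 and -0.32 without CW069 2. The matrix list was lost without AZ82 1, AZ82 2, CW069 2 or CW069 3 (0.0637 to 0.460), and spermatogonia without Control 2, AZ82 1, AZ82 2 or any CW069 library (0.0524 to 0.283), with a median of 0.06 without AZ82 2. The matrix median was 0.02 without AZ82 1 or CW069 2, 0.03 without AZ82 2 and 0.12 without AZ82 3.

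Other lists passed between the inhibitors only with a library left out. The elongating spermatid list had a median of -0.09 with all libraries (camera adjusted p = 0.143) and -0.08 without Control 3, where it had the smallest adjusted p of the lists (3.26e-06; adjusted p = 0.798 with an estimated correlation). Red blood cell genes had 0.36 (0.154) and, without Control 3, 0.37 (0.0393; adjusted p = 0.798 with an estimated correlation). Macrophages passed without AZ82 1 (-0.14; 0.0215), peritubular genes without AZ82 3 (0.15; 0.00751), and immediate early genes (0.15; 0.00622) and ribosomal protein genes (-0.07; 0.00223) without CW069 1. Oxidative phosphorylation passed without AZ82 3 or CW069 1 (-0.04 in both; 0.0105 and 0.00359).

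edgeR called 0 genes higher and 0 lower between the inhibitors, with a smallest adjusted p of 0.255. At an unadjusted p under 0.05 there were 409 higher and 378 lower genes, 787 against 792 expected by chance; DESeq2 called 9 and 4, limma-voom 0 and 0. By the same rule the higher genes were the glycogen phosphorylase gene Pygb (0.68 ± 0.11), Mtarc2 (0.42 ± 0.08), Fetub (1.58 ± 0.30), Jund and the phosphatase gene Ptprd (0.58 ± 0.12); the lower ones after Hsd3b6 were the glutamine transporter gene Slc38a1 (-1.31 ± 0.28), Sema3b (-0.93 ± 0.20), the lysosomal glucosidase gene Gaa (-0.51 ± 0.11) and Fbxo43, a meiotic cell cycle inhibitor (-0.59 ± 0.13). Groups did not overlap in 11.3% of genes, against 10% by chance. Kifc1 differed by 0.04 (-0.22 to 0.30). A difference that misses the threshold does not show that the inhibitors act alike, since the median interval reached 0.28 to either side.

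The fold changes of AZ82 and CW069 against Control were correlated across genes (Pearson r = 0.525, Spearman rho = 0.559; genes are not independent replicates). Both use the same Control libraries, and unchanged groups simulated against them gave r from 0.463 to 0.518 and rho from 0.439 to 0.475. The covariance was 0.0326, against 0.0223 to 0.0261 in the simulations. At an unadjusted p under 0.05, 210 genes were higher with both inhibitors, against 88.3 on average in the simulations. Lower with both were 202, against 77.8, and 4 went opposite ways. The simulated groups also had fewer genes at that p: on average 373 and 372 higher, against the real 640 and 574. They had 377 and 378 lower, against 759 and 588. Independent groups of these sizes would share 23.2 higher and 28.2 lower genes, against 8.84 and 9.07 in the simulations. The raw overlaps thus do not by themselves show agreement beyond the shared Control libraries. On mean log2 CPM differences r was 0.539, and 47 of 100 regroupings of the 9 libraries into trios gave as high a value.

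Several lists close to KIFC1 function were not past the test. Mitotic and meiotic kinesins had medians of 0.0019 for AZ82 (adjusted p = 0.825) and -0.0020 for CW069 (0.918), over 15 members. Spindle checkpoint and kinetochore genes had -0.02 (0.484) and -0.02 (0.310) over 48, centrosome genes 0.0041 (0.723) and -0.0096 (0.820) over 39, and dynein and dynactin 0.03 (0.210) and 0.04 (0.310) over 32. Cell cycle genes had -0.07 (0.0619) and -0.05 (0.302) over 40, and targets of p53 -0.06 (0.228) and -0.06 (0.299) over 38. Meiotic spermatocyte genes had -0.02 (0.802) and -0.0074 (0.820) over 49. The apoptosis list, past the test after CW069, had -0.06 after AZ82 (0.0619), where it passed without Control 2 or AZ82 3 (0.0337 and 0.0320). Without Control 1, cell cycle genes passed after AZ82 (median -0.10; adjusted p = 0.0120) and after CW069 (-0.05; 0.0494), and spindle checkpoint genes after CW069 (-0.06; 0.0148). Cell cycle genes also passed after AZ82 without AZ82 1 (0.0438). The kinesin-14 list had 4 tested members, too few to test as a list.

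No list call in any of the 4 comparisons held with an estimated correlation, and with each library left out in turn an estimated correlation called 0 lists as well (smallest adjusted p = 0.0979). Fry called 0 lists in each comparison as moving on balance in 1 direction. Its mixed test, for genes that change in either direction, called 1 list after AZ82 (spermatogonia, adjusted p = 0.00775), 2 after CW069 (Leydig, 0.00176, and immediate early genes, 0.00310), 2 between the inhibitors (spermatogonia, 0.0118, and immediate early genes, 0.00341) and 6 for both inhibitors. Those 6 were the Leydig (0.0288), heat shock (0.0394), apoptosis and oxidative stress (0.0467 each), and cell cycle and immediate early gene lists (0.04998 each). Neither form of fry compares a list with other genes. Among other groupings of the same libraries, some gave as many lists as the inhibitors did: 12 in a split of the AZ82 and Control libraries against 11, 10 in one of the CW069 and Control libraries against 10, and 16 in a split of all libraries against 11. The median of the other splits was 8 lists, 8 lists and 7 lists, so most of these numbers also arose under other groupings. Between the inhibitors the real split gave 5 lists, against a median of 7 and a highest of 11 in the other splits.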

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

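The tests on Control 3 (its low level, length and GC content, RNA loss), those on Slc1a7 and those on CW069 1 and 2 were chosen only after the results were seen; so was counting genes at an unadjusted p under 0.05 in the splits of 6 libraries, while the other splits were not.

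CW069 and AZ82 differed from each other in 5 gene lists by the list test on the difference itself. As many lists were reached in 7 of 10 splits of these 6 libraries, the real one included. The median of the other splits was 7 lists, so the number of lists does not set the inhibitors apart. Median log2 differences, CW069 minus AZ82, were 0.13 for spermatogonia, 0.10 for Sertoli cells, -0.20 for the interferon response, 0.063 for extracellular matrix and -0.36 for adipocytes. All 5 had an adjusted p = 0.855 with an estimated correlation, and the doses differed. With a library left out, 1 of the 5, Sertoli cells, stayed past the test in each fit, and the adipocyte median ranged from -0.59 to 0.047. Only CW069 1 and 2, the closest pair, lay above all AZ82 libraries in the Sertoli list. CW069 3 (-0.06) lay below AZ82 2 and AZ82 3 (-0.02 and 0.00068).

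Elongating spermatid genes were higher in both inhibitor groups than in Control, with a median of 0.19. Without Control 3 that median was -0.00080 (adjusted p = 0.865), which is consistent with a low level in that 1 library as the main source; for AZ82 alone a median of 0.04 stayed past the test (adjusted p = 0.0220). A trend with transcript length or GC content does not account for Control 3: after its removal the list's median against Control 1 and 2 was -0.68, against -0.75 before, and 36 of 40 members had a length. Loss of intact RNA would tie the ratio to transcript length outside the germ cell lists as well, whereas that correlation across 15146 genes was 0.0627, within the -0.149 to 0.0949 of the other libraries. What stays open includes a difference in tissue sampled, in the animal, or in RNA handling or library preparation that leaves no trend with length. None of these was tested.

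Slc1a7 was lower in all 6 inhibitor libraries than in the 3 Control libraries. Too few reads is excluded, since the lowest Control library held 22 counts and the ratio's interval starts at 14.2. ICR mice are outbred, and different alleles carried by the animals of the groups may be the source: 4 of the 50 nearest tested genes, Ttc22 and Orc1 among them, had an unadjusted p under 0.01, as many as in 2.24% of other windows (median 1). Since Ttc22 and Orc1 prompted the idea, only 2 were not seen before, a number that 26.1% of windows reach, so an allele and an effect of the inhibitors cannot be told apart for Slc1a7. An effect of treatment remains a hypothesis.

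CW069 1 and 2 were closer than any other pair of libraries. The chi-square per degree of freedom between their counts was 3.48, above the 0.987 of a simulated library divided at random in 2 parts and below the 4.76 to 34.8 of other pairs. That excludes a random division of 1 library's reads. The simulated parts held no spread between sequencing runs, so the value cannot decide on 1 library sequenced in 2 runs. Among genes picked after their values were seen, Car3 had 104 and 23 counts in CW069 1 and 2, and Hba-a1 554 and 309. In 36 genes the highest count was at least 50 and at least 15 times the lowest. Of these, 31 lay within 3-fold in this pair, against 11 to 23 in other pairs. That would count against shared preparation alone only if such genes differ between animals, which was not tested. It is also close to the measure that marked the pair out, so shared preparation stays open. A source in 1 animal, or in animals of nearly the same genotype, stays open too. With adipocyte genes left out 1 gene differed 10-fold or more, against 11 to 29 in other pairs, but this is the measure that marked the pair out and cannot decide. With the pair summed, the lists past the test numbered 2 instead of 5 between the inhibitors, 12 instead of 10 for CW069 against Control, 13 instead of 11 for both inhibitors, and 11 as before for AZ82.

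Other splits of the same libraries were run for called genes, genes at an unadjusted p under 0.05 and lists past the test. With 6 libraries there are 10 splits, too few for a share under 0.05. For genes called by edgeR, 10 of 10 splits gave at least the real 0 in each of the 3 pairwise comparisons, and the highest other counts were 4 for AZ82 against Control, 2 for CW069 against Control and 3 for CW069 against AZ82. At an unadjusted p under 0.05, the real 1399 for AZ82 was reached in 1 of 10 splits, itself (highest other 1158), the real 1162 for CW069 in 2 of 10 (highest other 1312), and the real 787 between inhibitors in 3 of 10 (highest other 1102). For lists, the real 11 for AZ82 was reached in 2 of 10 splits (highest other 12), the real 10 for CW069 in 3 of 10 (highest other 10), and the real 5 between inhibitors in 7 of 10 (highest other 11). The median of the other splits was 8 lists, 8 lists and 7 lists. For both inhibitors against Control, each of the 84 splits was fitted with 1 coefficient per side. The 1 gene called was matched in 20 of 84 splits (highest other 9) and the 11 lists in 11 of 84 (highest other 16, median other 7), so chance is not excluded for either. The 1579 genes at an unadjusted p under 0.05 were matched in 2 of 84 splits, the real one included. That excludes chance only if the 9 libraries are independent, which the closeness of CW069 1 and 2 leaves in doubt; the highest other, 1752, set that pair with Control 3 against the rest, which points to a structure of the samples besides the groups. The correlation of the inhibitors' fold changes, 0.539 on mean log2 CPM differences, was matched in 47 of 100 regroupings drawn from 840 (highest other 0.680), so chance is not excluded.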

How the results depend on the processing

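CW069 1 and 2 summed, the length and GC removal, and an estimated correlation with a library left out were chosen after seeing the data; the other alternatives were planned. Of the 174 alternative counts of called genes, 131 stayed within 1.5 times the reported count, as did 58 of 108 list counts. Except for lower genes with both inhibitors, the reported gene counts were 0, so staying in that range meant 0 again. Where a 2-fold change was added to the adjusted threshold, that 0 was fixed in advance. The 131 thus mostly records that few genes were called. Kifc1 kept its direction in 78 of 79 values, the exception being -0.035 between the inhibitors without CW069 3 (highest with a library left out 0.089). Of the alternative medians of called lists, 528 kept their direction and side of the threshold, 463 were no longer past it and 8 reversed. Gene counts rested on the tool and on single libraries, and list counts on the correlation assumed between genes. At this depth and number of libraries, 53.7% of simulated 1.5-fold changes and 85.1% of 2-fold changes were recovered.

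For AZ82 against Control, called genes higher and lower numbered 2 and 3 with DESeq2 and 21 and 32 at an unadjusted p under 0.05 with a 2-fold change; 1 lower was called with library size only, limma-voom and robust dispersion. For CW069 against Control, DESeq2 gave 13 and 14, the unadjusted 2-fold threshold 31 and 40, and library size only 1 lower. For CW069 against AZ82, DESeq2 gave 9 and 4, only the groups compared 5 and 3, and the unadjusted 2-fold threshold 34 and 37. For both inhibitors against Control, DESeq2 gave 5 and 10 and the unadjusted 2-fold threshold 18 and 27. DESeq2 made 15.4% false calls in simulated data against 8.72% for edgeR. Only the groups compared means fewer samples; for the others the cause was not tested.

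With 1 library left out, counts of higher and lower genes ranged from 0 to 3 and 0 to 1 for AZ82, 0 to 6 and 0 to 1 for CW069, 0 to 3 and 0 to 1 between inhibitors, and 0 to 4 and 0 to 2 for both inhibitors. Without Control 2 the higher calls were Gm6866, Gm5592 and Gm2128 for AZ82, with Galnt17, Jund and Mex3b besides for CW069, and the lower call Frzb; Control 2 resembled the inhibitor libraries in the predicted genes and Frzb. Without CW069 3, Dchs1 and Galntl6 were among the calls for CW069 against Control (adjusted p = 0.00105 for both). That fit left CW069 1 and 2, the closest pair of libraries, as the CW069 group. Its p-values may therefore rest on samples that are not independent. Lists past the test ranged from 9 to 13 for AZ82, 5 to 11 for CW069, 1 to 7 between inhibitors and 10 to 15 for both. Pearson r ranged from 0.387 to 0.653 and Spearman rho from 0.427 to 0.670.

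With an estimated correlation 0 lists passed in each comparison, with all libraries or any 1 left out, and with fry 0, 0, 0 and 0. With CW069 1 and 2 summed, 2 lists passed between the inhibitors, with fewer samples. With the replicate block, 0 lower genes were called for both inhibitors against Control instead of 1, and 3 lists passed between the inhibitors instead of 5. The lost gene was Slc1a7, with a log2 fold change of -5.15 in that fit (edgeR adjusted p = 0.0738). Its adjusted p ranged from 4.55e-06 to 0.0761 over its 19 alternatives. The numbers do not pair the libraries: after group means were removed, same-number pairs correlated at -0.146 to 0.0427 and other pairs at -0.0870 to 0.168, and 1 of 9 libraries correlated best with its own number.

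With 1 library left out, 4 list medians reversed, with either correlation. Extracellular matrix after AZ82 ranged from -0.20 to 0.010 (without Control 1). Elongating spermatids ranged from -0.00027 to 0.28 after CW069 and from -0.00080 to 0.33 with both inhibitors, lowest without Control 3. Adipocytes between the inhibitors ranged from -0.59 to 0.047, highest without AZ82 2, where Lpl (-1.08 to 0.016), Car3 (-1.85 to 0.14) and Cidec (-2.45 to 0.52) reversed too. Kifc5b, at -0.00012 for AZ82, was 0.0088 with RLE size factors, 0.0027 with no filter, 0.0089 with DESeq2, 0.0034 with limma-voom and 0.0025 with the replicate block. With a library left out it ranged from -0.061 to 0.077 for AZ82, from -0.10 to 0.040 for CW069 and from -0.079 to 0.058 for both inhibitors, highest without Control 3 each time. Except where fewer samples were fitted, the cause was not tested.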

Other observations

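Some gene groups stood outside the comparisons above. Peritubular myoid and smooth muscle genes, which form the contractile wall of the tubules, had a median log2 fold change of 0.10 after CW069, with 14 of 16 members above 0, and 0.04 after AZ82; neither was past the test (camera adjusted p = 0.0659 and 0.779). After CW069 this list passed without Control 1 (0.0249), AZ82 3 (0.0485) or CW069 3 (0.0313). Adipocyte markers, a sign of fat taken with the tissue, had 0.21 after AZ82 (0.335) and -0.47 after CW069 (0.468), and passed after AZ82 without Control 1 (median 0.43; adjusted p = 0.0473) or AZ82 1 (0.37; 0.0438). In AZ82 2 the fat droplet gene Cidec was at 3.86 CPM and Car3 at 29.9 CPM, while the group mean of Car3 was 13.0 ± 14.7 CPM (SD, n = 3). Red blood cell genes had -0.51 after AZ82 (0.288), 0.04 after CW069 (0.881) and -0.22 with both inhibitors (0.720) over 5 members. Control 3 was low in this list, and without it the medians were -0.87 (5.08e-05), -0.24 (0.124) and -0.57 (0.000937). Those fits had an adjusted p = 0.467, 0.862 and 0.463 with an estimated correlation, which called 0 lists with any 1 library left out. Hba-a1 was at 14.5 ± 2.78 CPM after AZ82, 26.4 ± 9.97 CPM after CW069 and 27.8 ± 6.39 CPM in Control.

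The groups in this paragraph were not past the test against Control with all libraries. Heat shock genes had medians of 0.03 after AZ82 (adjusted p = 0.779) and -0.02 after CW069 (0.497), unfolded protein response genes -0.03 (0.723) and -0.01 (0.497), and autophagy genes 0.0068 (0.779) and -0.0013 (0.684). Cytosolic ribosomal protein genes had 0.0053 (0.779) and -0.03 (0.310) over 84 members, and passed after CW069 without CW069 1 (median -0.07; adjusted p = 0.000730). Cholesterol synthesis genes had 0.06 (0.723) and 0.0083 (0.820), endothelial genes 0.03 (0.505) and 0.03 (0.964), and inflammatory cytokines -0.06 (0.442) and -0.04 (0.310). Neutrophil and lymphocyte genes had 0.08 (0.628) and -0.09 (0.955), epididymal epithelium genes 0.10 (0.288) and 0.0011 (0.885), and transport and ciliary kinesins 0.08 (0.442) and 0.05 (0.820). The interferon list, which differed between the inhibitors, had 0.07 after AZ82 (0.288) and -0.11 after CW069 (0.103) against Control. It passed after AZ82 without AZ82 1 (0.19; 0.00265), and after CW069 without Control 2 (-0.15; 0.0360) or CW069 2 (-0.23; 0.00406).

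In a few genes Control 2 stood at the level of the inhibitor libraries. The predicted gene Gm6866 was at 13.5 CPM in Control 2 against 0.414 and 0.466 CPM in Control 1 and 3, with 9.21 to 12.5 CPM after AZ82 and 15.1 to 17.7 CPM after CW069. Frzb, which encodes a secreted Wnt antagonist, was at 14.2 CPM in Control 2 against 50.9 and 36.9 CPM in Control 1 and 3, with 15.1 to 18.5 CPM in both inhibitor groups. These genes were chosen after their values were seen.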
